A study of Mus musculus with 8 samples.

How the data were processed

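Gene expression was measured in the inguinal mammary gland tissue of gonadectomized virgin mice (Mus musculus), 12 to 13 weeks old per the labels. Gonadectomy removes the ovaries as the main source of estrogen. Mice received 17β-estradiol (E2), the main circulating estrogen, under the skin 1, 3, 6, 12, 18 or 24 h before tissue collection, or a vehicle solution. The labels give the dose with the number 0.05 and with both a microgram and a milligram unit, so no dose is stated here. There were 8 arrays, of which 2 came from vehicle groups, both labelled 24 h, and 6 from E2-treated groups with 1 array per time. The times were taken from the sample titles, while the description of every sample, those titled 1 to 18 h included, reads 24 h, a conflict that the sources used here do not settle. The labels say that tissue of all mice of a group was collected, and whether RNA of several mice was pooled on an array is not given in the sources used here.

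Per the labels, total RNA was extracted with Trizol, made into biotin-labelled cRNA and hybridised to Affymetrix arrays with 1 colour. The submitters' processing notes name GCOS 1.0 and RMA, without the role or order of each. The deposited values are intensity values for 45101 probe sets, from 13.8 to 23591, on a linear scale. The quartiles were nearly equal on all 8 arrays, with medians between 173.9 and 180.49, so the authors had normalized the arrays together. No further normalization was applied, and log2 was taken of the deposited intensity values. The largest distance of an array's median from the vehicle mean was 0.028 on the log2 scale. The number of arrays limits the precision of every value.

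The 64 control probe sets were left out, 34945 probe sets carried 1 gene symbol, 932 carried several and 9160 carried none. Symbols were compared through Entrez identifiers with the RefSeq annotation of mouse assembly GRCm38.p6, in which 34741 of the 34945 matched and 0 symbols were updated. Genomic positions were not used. Each of the 18193 genes was represented by its probe set with the highest mean over all arrays, a choice that mattered for the 9010 genes with more than 1 probe set. Genes with a mean at or above the 40th percentile (7.72 on the log2 scale, an intensity of 211) were tested, which left 10916. The log2 ratio of 3' to 5' control probe sets lay between 0.27 and 0.36 for Actb and between -0.02 and 0.04 for Gapdh.

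The E2 arrays were placed in an early window of 3 arrays (1, 3 and 6 h) and a late window of 3 arrays (12, 18 and 24 h). Linear models with 3 windows, vehicle included, and 5 residual degrees of freedom were fitted in limma 3.58.1 under R 4.3.3, with a mean-variance trend in the empirical Bayes step. Each comparison was adjusted by Benjamini-Hochberg over the 10916 genes, and a gene was counted as changed at an adjusted p below 0.05. All p-values from limma are two-sided. They measure the spread between these arrays, which may be technical or between pools of mice. The windows place different times in 1 group, so that change within a window counts as spread. Because 1 array stood for each time, single times were described by the genes at least 2-fold from both vehicle arrays in the same direction, a count without a test and without a replicate check. A limma fit with 7 group means and 1 residual degree of freedom, which assumes that each single array varies as the vehicle arrays do, was an alternative for the single times. The time course in the plots uses evenly spaced time labels.

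Of 33 gene lists (pathways, hormone response genes and cell type markers), 31 with at least 5 tested genes were compared with all other genes by camera in limma, with a preset correlation of 0.01 and adjustment over the 31 lists. Camera with an estimated correlation was the alternative for this question. Fry, also run, asks whether the genes of a list moved one way, or in its mixed form whether they changed in either direction. It compares a list with no other genes, so that its counts answer a different question. Counts of genes adjusted over the list alone are also given. The windows, lists, thresholds, alternatives and the rule for naming genes were set before the data were examined. That rule took the 12 largest rises and the 12 largest falls among changed genes whose arrays did not overlap between the groups, or the 5 smallest p-values of a direction where fewer had changed. It also took a set of genes of estrogen response and mammary biology, the 3 largest rises and falls per time, and up to 4 members per list with the largest difference. Symbols that are clone or model names were passed over.

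Each choice was varied singly. The variants were no level filter, a filter at the 60th percentile, quantile normalization, arrays centred on their median, the mean of a gene's probe sets, no trend, robust empirical Bayes (with statmod 1.5.0), array weights, marker means of lymphocytes, skeletal muscle or adipocytes as a covariate, a slope on log2 hours, other fold thresholds and each array left out. Where an array was left out and a group had 1 array, that array was assumed to vary as the others do. Skeletal muscle and lymphocyte means together as covariates, and the counts per time without the skeletal muscle list, were added after the data were seen.

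The fits were tested on simulated data for 10916 genes in 10 runs with the same 8 arrays. Changes of 1.5-fold, 2-fold and 3-fold between late and early windows were recovered for 98.7%, 99.9% and 100% of altered genes, with 5.28% false calls. For the early window against vehicle the shares were 98.1%, 99.9% and 100%, with 5.79% false calls. For the late window against vehicle they were 98.2%, 100% and 99.8%, with 5.96% false calls. The fit with 7 group means recovered 91.8%, 99.6% and 100% at 3 h, with 13.1% false calls. Among unchanged lists, 1 was called over 10 runs of 31 lists. The simulated arrays carried no shared variation between genes such as a change in tissue composition. In the window simulations a change was equal on all arrays of its window. Recovery of genes that rise or fall within a window was therefore not tested. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15. Probe sets without 1 gene symbol were left out of the tests of genes and lists, were fitted separately and are reported only as counts.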

Results

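Transcript levels were measured on 8 arrays of inguinal mammary gland tissue from gonadectomized mice, to follow how the tissue responded to 17β-estradiol (E2) over a day. The vehicle group had 2 arrays, and E2 was represented by 1 array at each of 6 times from 1 to 24 h as the sample titles give them (the descriptions read 24 h for all), grouped into an early window (1, 3 and 6 h, n = 3) and a late window (12, 18 and 24 h, n = 3). Both vehicle arrays were labelled 24 h, so the times from 1 to 18 h had no vehicle array of their own. At those times an effect of E2 cannot be told apart from one of the injection itself or of the time of day. Median intensities of the arrays lay between 173.9 and 180.49. The vehicle arrays differed by an SD of 0.13 over the log2 differences of 10916 genes, with 0 genes 2-fold apart and 18 genes 1.5-fold apart. The closest pair of arrays was E2 18 h and E2 24 h, with an SD of 0.0901.

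Markers of other tissues varied between the arrays. Skeletal muscle markers, 22 genes of the contractile apparatus and muscle metabolism, averaged 0.36 higher on the log2 scale in vehicle 1 than in vehicle 2. Against the vehicle mean they averaged 0.72 at 1 h, 0.57 at 3 h, 1.13 at 6 h, 0.18 at 12 h, 0.75 at 18 h and 0.86 at 24 h. B lymphocyte markers (17 genes) averaged -0.29 in vehicle 1 against vehicle 2, and lay at 0.15, 0.13, -0.14, 0.12, -0.41 and -0.41 at the 6 times. T lymphocyte markers (19 genes) averaged -0.17 in vehicle 1 against vehicle 2 and -0.32 at 18 h and -0.24 at 24 h. Genes of fatty acid and triglyceride synthesis averaged 0.20 higher, and genes of cholesterol synthesis 0.18 higher, in vehicle 1 than in vehicle 2.

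At 1 h after E2, the genes farthest above both vehicle arrays were Gadd45g, a growth arrest and DNA damage response gene, Errfi1, a feedback inhibitor of the epidermal growth factor receptor, and Ccn1, a secreted matricellular protein. Gadd45g was 3.08-fold higher than the vehicle mean, at 1.74 and 1.51 above the vehicle arrays on the log2 scale. Errfi1 was 2.78-fold higher and Ccn1 2.49-fold higher. Genes of the immediate early response, which are transcribed within minutes of a stimulus, averaged 0.30 above the vehicle mean, with 24 of 27 above both vehicle arrays. In all, 6 genes were at least 2-fold higher than both vehicle arrays and 0 were at least 2-fold lower. At 1.5-fold there were 35 genes at 1 h, against 5 that set vehicle 1 and 5 that set vehicle 2 apart from the other vehicle array and the 1 h array. The limma fit with 7 group means called 7 genes, these 6 among them, with adjusted p = 0.0291 for Gadd45g, 0.0175 for Errfi1 and 0.0291 for Ccn1. The other gene it called was Foxa1, the only one lower, at -0.95 (adjusted p = 0.0454). The count was 19 when set against vehicle 2 alone, without vehicle 1, and 7 without vehicle 2.

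At 3 h, Krt4, a keratin of stratified epithelia, was 10.6-fold higher than the vehicle mean, at 3.30 and 3.51 above the vehicle arrays on the log2 scale. Acot1, a cytosolic acyl-CoA thioesterase, was 5.71-fold higher, and Pgr, the progesterone receptor and a known estrogen receptor target, was 2.43 higher on the log2 scale. Foxa1, a pioneer transcription factor that opens chromatin for the estrogen receptor, lay at -2.63 against the vehicle mean, at -2.59 and -2.67 against the vehicle arrays. Tlcd4 lay at -2.22 and Lratd1 at -1.52. Gata3, a luminal transcription factor, lay at -0.86, and Esr1, the estrogen receptor alpha, at -0.30. The other 21 luminal epithelial markers averaged -0.10 at 3 h. At this time 15 genes were at least 2-fold higher and 6 at least 2-fold lower than both vehicle arrays. At 1.5-fold there were 87, against 4 and 5 with vehicle 1 or vehicle 2 as the odd one. The limma fit with 7 group means called 65 genes, all 21 of these included, with adjusted p = 0.000698 for Krt4, 0.00158 for Acot1, 0.00716 for Pgr, 0.000698 for Foxa1, 0.00385 for Tlcd4, 0.00716 for Lratd1 and 0.0324 for Gata3. It did not call Esr1 (adjusted p = 0.336).

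At 6 h, Krt4 was 5.76-fold higher than the vehicle mean, and Cxcl15, a chemokine made by epithelium, was 3.51-fold higher. Pgr was 1.60 above the vehicle mean on the log2 scale. Mb, the oxygen carrier myoglobin of muscle, was 3.08-fold higher, on the array whose skeletal muscle markers stood at 1.13. Cited1, a transcriptional coactivator that can bind the estrogen receptor, lay at -2.02, with -2.10 and -1.93 against the vehicle arrays. Tlcd4 lay at -1.43, Tmprss2, a membrane serine protease, at -1.28, Esr1 at -0.99 and Foxa1 at -0.90. In all, 20 genes were at least 2-fold higher and 3 at least 2-fold lower than both vehicle arrays, and at 1.5-fold there were 81, against 1 and 10 with vehicle 1 or vehicle 2 as the odd one. Without the genes of the skeletal muscle list 12 of the 23 were left, and without vehicle 1 the count was 44. The limma fit with 7 group means, which has 1 array at this time, called Krt4, Cxcl15, Cited1, Tlcd4, Esr1, Tmprss2, Pgr and Foxa1. It also called the muscle genes Neb, Ttn, Tcap, Tnni2, Acta1, Mybpc2 and Eno3, and did not call Mb, Atp2a1, Myl1 or Tnnc2.

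At 12 h, Cxcl15 was still 2.94-fold above the vehicle mean, and Krt8, a keratin of luminal epithelium, was 2.59-fold higher. Clca3a2, of a family of chloride channel regulators, was 2.64-fold higher, and Pgr was 1.30 above the vehicle mean on the log2 scale. C1qtnf3, a secreted protein of the complement C1q and tumor necrosis factor-related family, lay at -1.71, and Cited1 at -1.21. These were the 6 genes at least 2-fold from both vehicle arrays, 4 higher and 2 lower. At 1.5-fold the count was 23, against 6 and 4 for the vehicle arrays. The limma fit with 7 group means called 4 genes at this time, with adjusted p = 0.0135 for Cxcl15 and for Krt8 and 0.0379 for C1qtnf3. It did not call Clca3a2 (adjusted p = 0.125), Cited1 (adjusted p = 0.0557) or Pgr. Without vehicle 1 or without vehicle 2 the count was 10.

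At 18 h, Dmbt1, a mucosal scavenger receptor glycoprotein, was 2.64-fold higher than the vehicle mean and Clca3a2 was 2.51-fold higher, and at 24 h Mb was 2.77-fold higher. These 2 genes at 18 h and 1 gene at 24 h were all that lay at least 2-fold from both vehicle arrays. At 1.5-fold the counts were 25 at 18 h and 24 at 24 h, against 2 for vehicle 1 and 8 for vehicle 2 at either time. Krt4, at 0.08 and 0.29, and Foxa1, at 0.07 and -0.02, were near the vehicle mean at 18 and 24 h, and Pgr was at 0.64 and 0.16. The limma fit with 7 group means called 0 genes at 18 h and 0 at 24 h, with 637 and 699 genes at an unadjusted p below 0.05. Skeletal muscle markers averaged 0.86 at 24 h, and 0 genes remained at that time without the muscle list. Without vehicle 1 the counts were 20 at 18 h and 21 at 24 h, and without vehicle 2 they were 2 and 2.

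**Figure D1:**
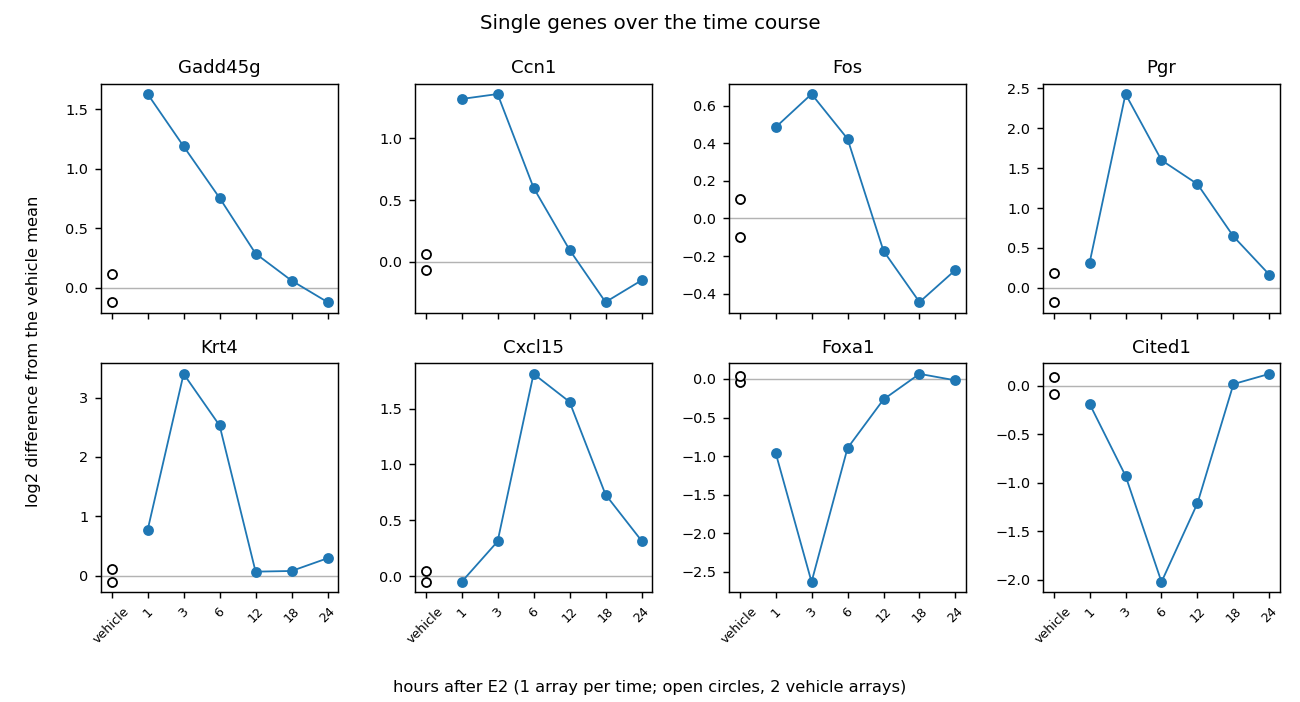
Log2 difference from the vehicle mean for 8 genes, with 1 filled circle per E2 array, open circles for the 2 vehicle arrays and evenly spaced time labels in hours. Gadd45g stood at 1.63 at 1 h, Krt4 peaked at 3.40 and Pgr at 2.43 at 3 h, Cxcl15 peaked at 1.81 at 6 h, and the lowest points of Foxa1 and Cited1 were -2.63 at 3 h and -2.02 at 6 h.

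The comparison of the early window with vehicle asked which transcripts differed over the first 6 h after E2 from the vehicle arrays, both labelled 24 h. Fos, a subunit of the transcription factor AP-1, lay 0.52 ± 0.0974 (SE) above vehicle on the log2 scale, Gadd45g 1.19 ± 0.212 above and Adamts1, a secreted protease known from the ovulatory response to progesterone, 0.78 ± 0.141 above (n = 3 against 2). Ppp1r3c, a subunit that targets a phosphatase to glycogen, lay at 0.52 ± 0.0634, Nfil3, a basic leucine zipper transcription repressor, at 0.48 ± 0.086 and Got1, the cytosolic aspartate aminotransferase, at 0.30 ± 0.0522. Below vehicle lay Lratd1 at -0.97 ± 0.218, Gata3 at -0.60 ± 0.156, the histone deacetylase Hdac11 at -0.31, the noncoding transcript Airn at -0.28 and the transcription factor Tfap4 at -0.22. None of these genes passed the test. In limma 0 of 10916 genes reached an adjusted p below 0.05. The smallest adjusted p, 0.127, was that of Ppp1r3c, while 587 genes, 397 higher and 190 lower, had an unadjusted p below 0.05, where chance alone gives 546. The adjusted p was 0.345 for Fos, Gadd45g, Adamts1, Nfil3 and Got1, 0.5 for Lratd1 and 0.547 for Gata3. The early arrays did not overlap the vehicle arrays in 19.9% of genes, where 3 against 2 arrays give 20% by chance. The count was 49 without the 1 h array, 3 without the 3 h array, 8 without the 6 h array and 0 without any other array.

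As groups, immediate early genes rose over the early window against all other genes, and genes of lipid synthesis fell. Immediate early genes averaged 0.25 above vehicle, with 25 of 27 higher and 6 of them past the test when adjusted over the list alone (camera adjusted p = 5.84e-11; adjusted p = 0.369 with an estimated correlation). Fatty acid and triglyceride synthesis averaged -0.15, with 23 of 27 genes lower, among them Acss2, an acetyl-CoA synthetase, at -0.38 and the desaturase Scd2 at -0.38 (adjusted p = 1.21e-10; adjusted p = 0.369 with an estimated correlation). Cholesterol synthesis averaged -0.13, with 17 of 20 lower, among them Sc5d, a sterol desaturase, at -0.40 and Insig1, a brake on sterol synthesis, at -0.36 (adjusted p = 5.29e-07; adjusted p = 0.369 with an estimated correlation). In both lipid lists 0 genes passed when adjusted over the list alone, and vehicle 1 exceeded vehicle 2 by 0.20 and 0.18. Without vehicle 1 the fatty acid and cholesterol lists averaged -0.05 and -0.04, which ended the cholesterol call, and without vehicle 2 they averaged -0.25 and -0.22. The fatty acid call ended with muscle and lymphocyte marker means as covariates.

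Glucocorticoid-responsive genes averaged 0.20 above vehicle in the early window, with 16 of 20 higher and 4 past the test when adjusted over the list alone (camera adjusted p = 0.000128; adjusted p = 0.369 with an estimated correlation). Errfi1 lay at 0.90 and Pdk4, an inhibitor of glucose oxidation, at 0.67. Myoepithelial markers averaged 0.14, with 10 of 10 higher, among them the basal keratin Krt5 at 0.29 and Sfn at 0.30 (adjusted p = 0.000262; adjusted p = 0.369 with an estimated correlation). Ribosome biogenesis averaged 0.07 (adjusted p = 0.00426; adjusted p = 0.679 with an estimated correlation), cytokines and chemokines 0.10 (adjusted p = 0.0113; adjusted p = 0.457 with an estimated correlation) and extracellular matrix genes 0.09 (adjusted p = 0.0119; adjusted p = 0.679 with an estimated correlation). Socs3, a feedback inhibitor of cytokine signalling, lay at 0.61, and Plod2, which modifies collagen, at 0.73. Skeletal muscle markers averaged 0.81, with 21 of 22 higher and 20 past the test when adjusted over the list alone (adjusted p = 6.81e-25; adjusted p = 0.369 with an estimated correlation), and brown fat markers 0.22 (adjusted p = 0.0385; adjusted p = 0.679 with an estimated correlation), with the uncoupling protein gene Ucp1 at 0.89. Of the 31 lists 10 were called, 8 higher and 2 lower, and 0 with an estimated correlation. Fry, which asks whether a list moved one way and compares it with no other genes, called 0. Without vehicle 1 the glucocorticoid and ribosome (mean 0.04) calls ended and brown fat markers averaged 0.39, and without vehicle 2 the cytokine, matrix and brown fat (mean 0.05) calls ended. The ribosome, cytokine (mean 0.07), matrix (mean 0.05) and brown fat calls also ended without the 6 h array, and the brown fat call without the 3 h or the 12 h array. With the muscle marker mean as a covariate matrix genes were called in the opposite direction, with a mean of -0.05 (adjusted p = 0.000111), and the cytokine mean turned to -0.0052 (adjusted p = 0.401). Cytokines were called in the opposite direction with muscle and lymphocyte covariates together (mean -0.411, adjusted p = 0.00394). The brown fat call ended with the muscle covariate, as it did with the adipocyte covariate and with the filter at the 60th percentile. The matrix call also ended with quantile normalization, and the glucocorticoid and ribosome calls with muscle and lymphocyte covariates together.

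The late window against vehicle asked which transcripts differed between 12 and 24 h after E2. Krt8 lay 0.94 ± 0.213 (SE) above vehicle on the log2 scale, Fdps, which makes farnesyl pyrophosphate for sterol synthesis, 0.54 ± 0.113, the whey acidic protein family gene Wfdc18 0.43 ± 0.0988, Ltf, the secreted iron-binding protein lactoferrin, 0.40 ± 0.055, and Muc1, an apical mucin of luminal cells, 0.34 ± 0.063 (n = 3 against 2). Below vehicle lay Vapb, a tether protein of the endoplasmic reticulum, at -0.46 ± 0.0873, Cwc25 at -0.39, Nectin3, an adhesion protein, at -0.32, Msl2 at -0.31 and Ptger4, a prostaglandin E2 receptor, at -0.27. The other Vapb probe sets lay between -0.124 and -0.059 on the 12, 18 and 24 h arrays. None of these genes passed the test. In limma 0 of 10916 genes reached an adjusted p below 0.05, and the smallest, 0.35, was that of Ltf. The others had an adjusted p of 0.634, and 830 genes, 306 higher and 524 lower, had an unadjusted p below 0.05 where chance alone gives 546. The late arrays did not overlap the vehicle arrays in 24.4% of genes, where 3 against 2 arrays give 20% by chance. The count was 0 with any single array left out.

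As groups, epithelial and lipid synthesis genes rose in the late window against vehicle. Luminal epithelial markers averaged 0.21, with 18 of 22 higher and 3 past the test when adjusted over the list alone, and Krt19 lay at 0.53 and Krt18 at 0.49 (camera adjusted p = 6.05e-08; adjusted p = 0.0672 with an estimated correlation). Milk proteins and secretory differentiation genes averaged 0.18, with 10 of 12 higher and 2 past the test when adjusted over the list alone, and the milk sugar synthase subunit Lalba lay at 0.34 (adjusted p = 7.74e-06; adjusted p = 0.298 with an estimated correlation). Myoepithelial markers averaged 0.13, with 9 of 10 higher and the oxytocin receptor gene Oxtr at 0.30 (adjusted p = 4.22e-05; adjusted p = 0.298 with an estimated correlation). Fatty acid and triglyceride synthesis averaged 0.17, with 23 of 27 higher and Mlxipl, a carbohydrate-responsive transcription factor, at 0.42 (adjusted p = 2.79e-09; adjusted p = 0.447 with an estimated correlation). Cholesterol synthesis averaged 0.16, with 16 of 20 higher and 3 past the test when adjusted over the list alone, and Sqle, squalene epoxidase, lay at 0.41 (adjusted p = 3.65e-06; adjusted p = 0.447 with an estimated correlation). For these lipid lists the difference between the vehicle arrays was 0.20 and 0.18. Without vehicle 1 the fatty acid and cholesterol lists averaged 0.28 and 0.24, without vehicle 2 they averaged 0.07 and 0.07, and without the 12 h array milk proteins averaged 0.10. The cholesterol call ended with muscle and lymphocyte marker means as covariates.

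Oxidative phosphorylation genes averaged 0.08 above vehicle in the late window, with 33 of 34 higher and Uqcrc1, of complex III, at 0.19 (camera adjusted p = 7.39e-10; adjusted p = 0.531 with an estimated correlation). Skeletal muscle markers averaged 0.60, with 22 of 22 higher and 16 past the test when adjusted over the list alone (adjusted p = 2.2e-17; adjusted p = 0.447 with an estimated correlation), and brown fat markers 0.24 (adjusted p = 0.000311; adjusted p = 0.447 with an estimated correlation). B lymphocyte markers averaged -0.23, with 17 of 17 lower (adjusted p = 0.00038; adjusted p = 0.698 with an estimated correlation), T lymphocyte markers -0.18, with 17 of 19 lower (adjusted p = 0.000641; adjusted p = 0.698 with an estimated correlation), and macrophage markers -0.08, with 22 of 24 lower (adjusted p = 0.00115; adjusted p = 0.698 with an estimated correlation). Immediate early genes averaged -0.08, with 21 of 27 lower (adjusted p = 0.0257; adjusted p = 0.698 with an estimated correlation). Of the 31 lists 12 were called, 8 higher and 4 lower, and 0 with an estimated correlation, and fry called 0. The macrophage call ended without vehicle 1 or the 12 h array (mean -0.05), and the immediate early call without vehicle 1 or the 18 h array (mean -0.04), while oxidative phosphorylation averaged 0.05 without the 12 h array and brown fat markers 0.40 without vehicle 1 and 0.07 without vehicle 2. Both lymphocyte calls ended without vehicle 2, with means of -0.09 for B and T lymphocytes, against B lymphocyte means of -0.38, -0.41, -0.15 and -0.14 without vehicle 1, 12 h, 18 h and 24 h, and T lymphocyte means of -0.28 and -0.11 without 12 h and 18 h. With the muscle marker mean as a covariate B lymphocyte markers were called in the opposite direction, with a mean of 0.199 (adjusted p = 1.78e-08), so that the direction for this list was not settled. With that covariate the immediate early and T lymphocyte means turned to 0.04 (adjusted p = 0.954) and 0.06 (adjusted p = 0.0935), and the brown fat call ended. The immediate early call also ended with arrays centred on their median and with the lymphocyte or the adipocyte covariate.

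**Figure D2:**
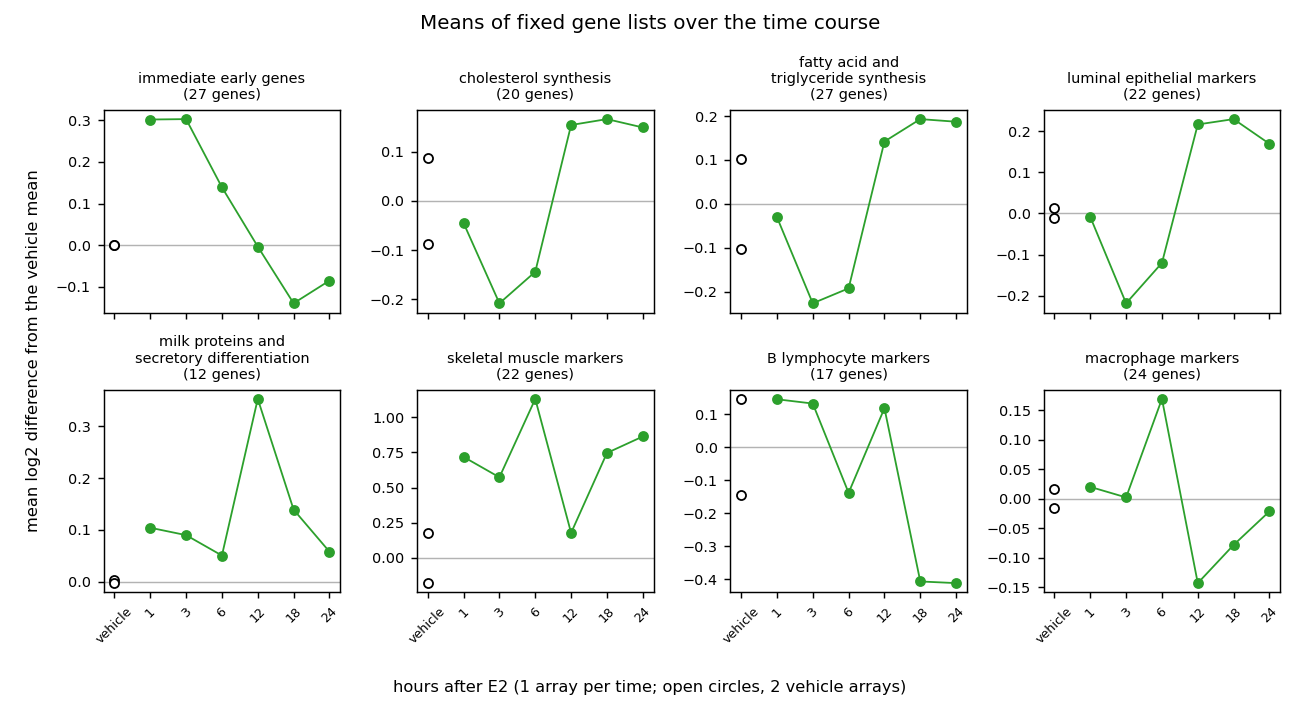
Mean log2 difference from the vehicle mean of 8 gene lists, with 1 filled circle per E2 array, open circles for the 2 vehicle arrays and evenly spaced time labels in hours. Immediate early genes went from a mean of 0.30 at 1 h to -0.14 at 18 h, lipid synthesis lists were lowest at 3 h (-0.23 and -0.21), and muscle markers ranged from 0.18 at 12 h to 1.13 at 6 h.

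The late against the early window asked how transcript levels moved on with time, and here 60 genes changed. Without vehicle arrays at the times from 1 to 18 h, a change with time that does not need E2 cannot be told apart. Fos fell by 0.82 ± 0.0871 (SE) on the log2 scale (limma adjusted p = 0.0199, n = 3 against 3), and Junb changed by -0.59 ± 0.0916, Fosl2 by -0.63 ± 0.104 and Runx1 by -0.54 ± 0.0813. Ccn1 changed by -1.22 ± 0.183, Gadd45g by -1.11 ± 0.189, Socs2, an inhibitor of growth hormone and cytokine signalling, by -0.90 ± 0.111, and the interleukin 17 receptor gene Il17ra by -0.90 ± 0.146. Tfrc, the transferrin receptor for iron uptake, changed by -0.80 ± 0.0821, the matricellular gene Thbs1 by -0.78 ± 0.126, Adamts1 by -0.75 ± 0.126 and Acot1 by -1.65 ± 0.277. Genes that rose included Krt8 (1.15 ± 0.19), the mitochondrial reductase gene Mtarc1 (1.04 ± 0.155) and Agpat2 (0.53 ± 0.074), an enzyme of triglyceride assembly. Some genes had other probe sets above the level filter with smaller differences. For Runx1 these ran from -0.518 to 0.0441, for Fosl2 the other lay at -0.164 and for Mtarc1 at 0.304. For Tfrc the other lay at -0.462, and for Socs2 they lay at -0.223 and -1. Those of Krt8 (1.21 and 1.06), Il17ra (-0.865) and Thbs1 (-0.626) lay near the values given.

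Several enzymes of cholesterol and fatty acid synthesis were among the genes that rose from the early to the late window. Cyp51 rose by 0.71 ± 0.112 (SE) on the log2 scale, Fdps by 0.68 ± 0.101, Sc5d by 0.64 ± 0.0983 and Sqle by 0.58 ± 0.098, all enzymes of the sterol pathway, with Acss2 at 0.74 ± 0.129 and Scd2 at 0.71 ± 0.121 for fatty acids (limma adjusted p between 0.0406 and 0.044). Prune2 rose by 0.65 ± 0.11, Tlcd2 by 0.62 ± 0.087 and Cyp1a1, a monooxygenase induced through the aryl hydrocarbon receptor, by 0.56 ± 0.0909. Other probe sets above the level filter lay at 0.733 and 0.466 for Acss2 and 0.586 and 0.331 for Sc5d. For Scd2 they lay at 0.675 and 0.811, and for Prune2 the other lay at 0.476. The adjusted p was 0.0199 for Tfrc, 0.0265 for Socs2, 0.041 for Gadd45g and 0.0406 or 0.0407 for the other named genes except Acss2 (0.044) and Scd2 (0.0414).

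In all, 27 genes rose and 33 fell in the late against the early window, 5 of them at least 2-fold, and all 60 had late arrays that did not overlap the early ones. Of all 10916 genes 24% did not overlap, where chance gives 10% for 3 against 3. Without the 18 h array or without the 24 h array 0 genes passed, without the 3 h array 8, without the 12 h array 13, without the 1 h array 232, and without vehicle 1 or without vehicle 2 37 genes passed. Leaving out either vehicle array leaves 1 that adds nothing to this difference or its spread, so those fits amount to 1 alternative. The fit with muscle and lymphocyte marker means as covariates gave 0. The balance of rises and falls depended on the processing. Rises outnumbered falls with quantile normalization (20 and 12), with the mean of a gene's probe sets (13 and 10), without vehicle 1 or without vehicle 2 (24 and 13 in either case) and without the 1 h array (119 and 113). Falls were more than 2 times the rises with the lymphocyte covariate (4 rises and 31 falls), the muscle covariate (219 and 906), array weights (520 and 1694) and the slope on log2 hours (0 and 9), and without the 3 h (2 and 6), 6 h (15 and 54) or 12 h array (3 and 10).

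**Figure D3:**
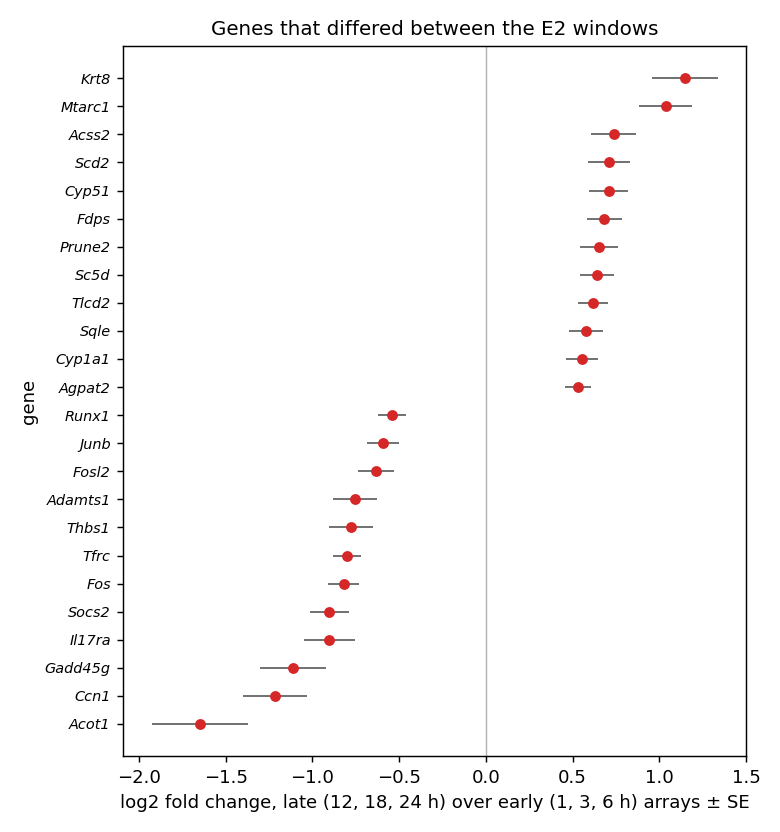
Log2 fold change of the late over the early E2 arrays, with its SE as a bar, for the 12 largest rises and the 12 largest falls among the 60 genes that passed the test, with genes named only by a clone number left out (n = 3 against 3). Values run from -1.65 for Acot1 to 1.15 for Krt8.

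As groups, luminal epithelial markers and lipid synthesis genes rose and immediate early genes fell from the early to the late window. Luminal epithelial markers averaged 0.32, with 18 of 22 higher, 3 past the test over all genes and 8 when adjusted over the list alone (camera adjusted p = 3.39e-09; adjusted p = 0.0459 with an estimated correlation). Krt19 lay at 0.77 and Krt18 at 0.76, with adjusted p = 0.0737 and 0.0722, and Foxa1 at 1.42 ± 0.375 (adjusted p = 0.119). Fatty acid and triglyceride synthesis averaged 0.32, with 25 of 27 higher, 3 past the test over all genes and 20 when adjusted over the list alone (adjusted p = 6.19e-19; adjusted p = 0.33 with an estimated correlation). Cholesterol synthesis averaged 0.29, with 17 of 20 higher, 5 past the test over all genes and 13 when adjusted over the list alone (adjusted p = 9.97e-12; adjusted p = 0.33 with an estimated correlation). Vehicle 1 exceeded vehicle 2 in these lipid lists by 0.20 and 0.18, and the vehicle arrays differed by -0.02 in luminal markers. Immediate early genes averaged -0.32, with 22 of 27 lower, 6 past the test over all genes and 21 when adjusted over the list alone, where 1 other gene was higher (adjusted p = 3.62e-09; adjusted p = 0.336 with an estimated correlation).

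Smaller shifts from the early to the late window were called in other lists. Ribosome biogenesis averaged -0.14, with 29 of 31 lower (camera adjusted p = 0.000165; adjusted p = 0.585 with an estimated correlation), and Nop58, of small nucleolar ribonucleoproteins, lay at -0.49. Extracellular matrix genes averaged -0.14, with 33 of 39 lower (adjusted p = 0.00346; adjusted p = 0.585 with an estimated correlation), and fibroblast markers -0.10, with 17 of 20 lower and the hyaluronan synthase Has2 at -0.33 (adjusted p = 0.00619; adjusted p = 0.585 with an estimated correlation). Macrophage markers averaged -0.15, with 24 of 24 lower (adjusted p = 8.67e-05; adjusted p = 0.585 with an estimated correlation). B lymphocyte markers averaged -0.28, with 17 of 17 lower (adjusted p = 0.000815; adjusted p = 0.585 with an estimated correlation), and T lymphocyte markers -0.18, with 18 of 19 lower (adjusted p = 0.00611; adjusted p = 0.585 with an estimated correlation). Oxidative phosphorylation averaged 0.05, with 31 of 34 higher (adjusted p = 2.04e-05; adjusted p = 0.585 with an estimated correlation), adipocyte markers 0.03, with 12 of 20 higher (adjusted p = 0.00852; adjusted p = 0.585 with an estimated correlation), and milk proteins and secretory differentiation 0.10, with 9 of 12 higher (adjusted p = 0.00217; adjusted p = 0.517 with an estimated correlation). In the last group Ltf rose by 0.39 ± 0.0492 (SE, adjusted p = 0.0265), whereas Stat5a, which carries the prolactin signal, lay at -0.36. Skeletal muscle markers averaged -0.21 (adjusted p = 0.135). Of the 31 lists 13 were called, 6 higher and 7 lower, and 1 with an estimated correlation (luminal epithelial markers), and fry called 2 (luminal epithelial markers and immediate early genes). Other splits of the 6 E2 arrays into 3 and 3 gave up to 16 called lists, so the count of 13 is not particular to these windows. The matrix and fibroblast calls ended without the 6 h or the 12 h array, the macrophage call without the 12 h array (mean -0.09 without 6 h), the milk protein call without the 12 h array (mean 0.02, and 0.165 without 24 h) and the T lymphocyte call without the 18 h array (mean -0.11, and -0.28 without 12 h). Without 12 h B lymphocyte markers averaged -0.455, oxidative phosphorylation averaged 0.033, 0.024 and 0.076 without 3, 12 and 24 h, and adipocyte markers averaged 0.060, 0.015 and 0.077 without 1, 3 and 24 h and lost their call at 0.0056, 0.00040 and 0.0035 without 6, 12 and 18 h. With muscle and lymphocyte marker means as covariates the macrophage and fibroblast means turned to 0.03 and the adipocyte mean to -0.06, and with the muscle covariate alone the adipocyte mean was -0.0017. The matrix and milk protein calls ended with the muscle covariate and with both covariates, the ribosome call with both covariates, the fibroblast call with the muscle covariate, the matrix and fibroblast calls with array weights, and the fibroblast and T lymphocyte calls with the filter at the 60th percentile.

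Several genes known as estrogen targets or regulators of mammary growth did not pass the test in the windows. Pgr lay 1.45 ± 0.512 (SE) above vehicle in the early window (limma adjusted p = 0.851) and 0.70 ± 0.512 above in the late window (adjusted p = 0.702). Esr1 lay at -0.43 and -0.34 (adjusted p = 0.921 and 0.679), and Igf1, a growth factor made by stroma, at -0.11 and -0.30 (adjusted p = 0.978 and 0.648). The growth regulator Myc lay at 0.27 and -0.06 (adjusted p = 0.851 and 0.865), the cell cycle inhibitor gene Cdkn1a at 0.27 and 0.04 (adjusted p = 0.653 and 0.878) and the cell cycle gene Ccnd1 at 0.08 and -0.03 (adjusted p = 0.973 and 0.927). The proliferation marker Mki67 lay at -0.07 and -0.24 (adjusted p = 0.963 and 0.634) and the replication factor Mcm2 at 0.05 and 0.09 (adjusted p = 0.978 and 0.659). Hspa5, Xbp1, Stc2 and Per1 lay between -0.18 and 0.15 of vehicle in both windows. Greb1, Esr2, Wnt4 and Tnfsf11 were under the level filter and were not tested, and Areg had no probe set under its symbol. For Greb1, an estrogen receptor target, the probe set with the highest mean lay at 0.16 at 3 h and 0.14 at 6 h against the vehicle mean. Among its other probe sets, all with a lower mean, 1 lay at 1.45 and 1.44 and another at 0.74 and 0.18, values that were picked out after they were seen. The list of estrogen-responsive genes, 22 of 32 measured, was not called in the early window (mean 0.08, camera adjusted p = 0.379), in the late window (mean -0.01, adjusted p = 0.823) or between them (mean -0.09, adjusted p = 0.291). Its members went both ways, with an SD over genes of 0.556 in the early window and 0.428 between the windows. Adjusted over the list alone, 2 genes were higher and 1 lower in the early window, 0 in the late window, and 2 were higher and 4 lower between the windows, where 1 was called over all genes. The test of fry for change in either direction, which compares a list with no other genes, gave adjusted p = 0.0388 early, 0.735 late and 0.00327 between the windows. By that test 5, 2 and 14 of the 31 lists were called in these comparisons.

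All 6 E2 arrays together were compared with vehicle as a mean over the time course, which does not show what the single times share. Myoepithelial markers averaged 0.13 above vehicle, with 10 of 10 higher (camera adjusted p = 7.91e-07; adjusted p = 0.338 with an estimated correlation), and milk proteins and secretory differentiation 0.13, with 9 of 12 higher (adjusted p = 0.000151; adjusted p = 0.338 with an estimated correlation). Glucocorticoid-responsive genes averaged 0.14, with 17 of 20 higher (adjusted p = 0.000151; adjusted p = 0.349 with an estimated correlation). Skeletal muscle markers averaged 0.70, with 22 of 22 higher (adjusted p = 1.44e-31; adjusted p = 0.338 with an estimated correlation), and brown fat markers 0.23 (adjusted p = 0.000161; adjusted p = 0.403 with an estimated correlation). Oxidative phosphorylation averaged 0.05 (adjusted p = 7.09e-07; adjusted p = 0.781 with an estimated correlation), immediate early genes 0.09 (adjusted p = 0.015; adjusted p = 0.817 with an estimated correlation), luminal markers 0.04 (adjusted p = 0.0253; adjusted p = 0.338 with an estimated correlation) and T lymphocyte markers -0.09 (adjusted p = 0.0191; adjusted p = 0.969 with an estimated correlation). The means of these last 4 lists differed in sign between times, from -0.0056 to 0.13 for oxidative phosphorylation, 0.30 to -0.14 for immediate early genes, -0.22 to 0.23 for luminal markers and 0.06 to -0.32 for T lymphocyte markers. Of the 31 lists these 9 were called, 8 higher and 1 lower, and 0 with an estimated correlation, and fry called 0. Among single genes limma called 0 of 10916, with a smallest adjusted p of 0.653. At an unadjusted p below 0.05 there were 379 genes, fewer than the 546 that chance alone gives. The E2 arrays did not overlap the vehicle arrays in 4.5% of genes, where 6 against 2 arrays give 7.14% by chance. The count was 0 with any single array left out.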

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

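Tests of muscle and adipocyte content between the vehicle arrays, of the luminal share at 3 h and of other splits for gene lists were chosen only after the result was seen. The rule for a single sample far from its group could not be applied, since no group held 4 arrays.

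The late and the early window differed by a direct test in limma, with 60 genes changed and 13 gene lists shifted. Of the 10 splits of the 6 E2 arrays into 3 and 3, 1, the real one, gave 60 genes, and the highest of the others gave 0. For the lists, 5 of the 10 splits gave 13 or more, with 16 as the highest of the others. For the genes, 10 splits are too few for a share under 0.05. For the lists, other splits gave as many or more, so the count of 13 does not set the windows apart from other groupings.

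Among the genes that differed between the windows, those higher late on the log2 scale were Krt8 by 1.15, Mtarc1 by 1.04, Acss2 by 0.74, Scd2 by 0.71, Cyp51 by 0.71, Fdps by 0.68, Prune2 by 0.65, Sc5d by 0.64, Tlcd2 by 0.62, Sqle by 0.58, Cyp1a1 by 0.56 and Agpat2 by 0.53. The genes lower late were Runx1 at -0.54, Junb at -0.59, Fosl2 at -0.63, Adamts1 at -0.75, Thbs1 at -0.78, Tfrc at -0.80, Fos at -0.82, Socs2 at -0.90, Il17ra at -0.90, Gadd45g at -1.11, Ccn1 at -1.22 and Acot1 at -1.65. The lists that differed averaged 0.323 for fatty acid and triglyceride synthesis, 0.32 for luminal epithelial markers, 0.289 for cholesterol synthesis, 0.102 for milk proteins, 0.0505 for oxidative phosphorylation and 0.027 for adipocyte markers. Lower late were immediate early genes at -0.324, B lymphocyte markers at -0.279, T lymphocyte markers at -0.184, macrophage markers at -0.145, extracellular matrix at -0.14, ribosome biogenesis at -0.135 and fibroblast markers at -0.104.

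The difference between the vehicle arrays, neither of which received E2, was correlated with that between the late and early windows. The Pearson r was 0.366 across 10916 genes (genes are not independent replicates). Other splits of the E2 arrays gave r of 0.6, 0.478 and 0.377, so the correlation is not particular to the windows. Among the 60 changed genes, picked for their late minus early difference, r was 0.764 and the sign was the same in 47. Of these 60, 27 differed between the vehicle arrays by at least the SD of that difference over all tested genes. Skeletal muscle in the samples stays open as a source, since muscle markers differed by 0.358 between vehicle 1 and vehicle 2, and their late minus early difference of -0.21 lay within the spread between arrays (SE over arrays 0.269). Lymphocyte markers went the same way in both comparisons. B lymphocyte markers averaged -0.292 in vehicle 1 against vehicle 2 and -0.279 late against early. For T lymphocyte markers the values were -0.173 and -0.184. A different share of lymphocytes was not tested as a source and stays open. With the lymphocyte covariate 11 of the 60 genes kept their call. Between the vehicle arrays the fatty acid synthesis list and the adipocyte markers went opposite ways, with means of 0.2 and -0.101. The difference was 0.301 (SE over genes 0.0523). That SE comes from 1 pair of arrays and from genes that move together, so it does not measure the spread between arrays. A different share of adipocytes was therefore not decided. An unlabelled difference between the vehicle arrays, such as feeding, time of day or array handling, may account for part of the lipid synthesis shift and was not tested. A response to E2 with time, which the design names, stays open for the windows alone and cannot be the source of the difference between the vehicle arrays.

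Skeletal muscle markers averaged 0.701 higher in the 6 E2 arrays than in the 2 vehicle arrays. Levels of muscle genes also varied without E2, since 22 of 22 measured muscle genes differed in one direction between the vehicle arrays. These genes move together (estimated correlation 0.833), so the count amounts to 1 observation. It cannot tell muscle carried into the tissue from another source, and carried-in muscle stays open. A chance difference was not excluded, with an exact two-sided permutation p = 0.0714 over 28 splits, of which the smallest possible is 0.0357. An effect of E2 on muscle content or muscle genes stays open.

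The luminal transcription factor genes Foxa1 (-2.63) and Gata3 (-0.863) were lower on the 3 h array, while Pgr was higher (2.43) and Esr1 stood at -0.301. These are values of 1 array set against 2 vehicle arrays, without a replicate at 3 h. As a set the other 21 luminal markers did not fall on this array as far as Foxa1, with a mean of -0.103 (SE over genes 0.0724), above the bound of -1. They went both ways, with Krt8 (-0.542), Krt18 (-0.571) and Krt19 (-0.663) lower and Cldn4 (0.368) and Prom1 (0.313) higher. That SE comes from 1 array and does not measure the spread between arrays. A smaller share of luminal epithelium, or of a part of it, was therefore not decided. A faulty single probe set cannot be told apart for Foxa1 and Gata3, which have 1 probe set each, and for Esr1 the 1 other probe set above the level filter also lay below both vehicle arrays, at -0.19. Foxa1 was lower on the 1 h (-0.954) and 6 h arrays (-0.896) too, each 1 array set against the same 2 vehicle arrays. A transcriptional response to E2 may be the source and stays open.

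Among the 2585 probe sets above the level filter that carried no single gene symbol, which were left out of the tests of genes and lists, 8 were at least 2-fold from both vehicle arrays at 1 or more times. In a separate limma fit of these unassigned probe sets 12 differed between late and early windows, 5 higher and 7 lower.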

How the results depend on the processing

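Skeletal muscle and lymphocyte marker means together as covariates, and the counts per time without the muscle list, were chosen only after the result was seen. The 60 genes that changed between the windows kept their sign under every alternative that measured them, except 1 gene with both covariates. The luminal marker list was called between late and early under each of its 22 alternatives, with means from 0.269 to 0.479 and adjusted p from 7.51e-11 to 0.0459. Lists that make up a covariate have no value under it, and robust empirical Bayes does not alter camera. Where no cause is given, the cause was not tested. Genes near the level filter, where signal stands least above background, may limit the counts. Between late and early 67 genes were called without a level filter and 47 with the filter at the 60th percentile.

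The 60 genes between late and early became 32 with quantile normalization (28 shared), 23 with the mean of a gene's probe sets (19 shared), 2214 with array weights, 35 with the lymphocyte covariate (11 shared), 1125 with the muscle covariate, 18 with the adipocyte covariate, 0 with muscle and lymphocyte covariates together, 5 with a 2-fold minimum and 9 as a slope on log2 hours (1 shared). Leaving out each array gave 0 to 232. The 13 lists became 22 without a level filter, 7 with both covariates and 1 with an estimated correlation, and fry, which asks another question, gave 2. Of the 0 genes in the late window against vehicle, array weights gave 1 and the adipocyte covariate 2. The 0 genes in the early window became 1 without a level filter, 1 with the mean of probe sets, 27 with the lymphocyte covariate, 10 with the muscle covariate, 1 with the adipocyte covariate, and 0 to 49 with an array left out. For all E2 arrays the lymphocyte covariate gave 11 genes and the muscle covariate 14 lists in place of 9. An estimated correlation and fry each gave 0 lists in the late window, the early window and all E2 arrays against vehicle.

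Counts of genes 2-fold from both vehicle arrays, 6, 21, 23, 6, 2 and 1 at the 6 times, became 35, 87, 81, 23, 25 and 24 at 1.5-fold and 0, 7, 3, 1, 0 and 0 at 3-fold, by construction. The filter at the 60th percentile, with fewer genes, gave 3 at 1 h, 12 at 3 h, 14 at 6 h and 0 at 24 h. At 24 h no filter gave 5, quantile normalization 3 and the mean of probe sets 0. The limma fit with 7 group means gave 65 at 3 h, 40 at 6 h, 0 at 18 h and 0 at 24 h. Without the muscle list 12 were left at 6 h and 0 at 24 h. Leaving out a vehicle array gave 7 to 19 at 1 h, 27 to 44 at 6 h, 10 in either case at 12 h, 2 to 20 at 18 h and 2 to 21 at 24 h.

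Some list means reversed. With the muscle covariate these were, in the late window against vehicle, immediate early genes (0.0375), lipolysis (0.0854), B lymphocytes (0.199) and T lymphocytes (0.0633), in the early window cytokines (-0.00518), extracellular matrix (-0.0517), macrophages (-0.0983) and fibroblasts (-0.0341), and between the windows adipocyte markers (-0.00166). With muscle and lymphocyte covariates they were immediate early genes (0.0278) and lipolysis (0.088) late, cytokines (-0.411), extracellular matrix (-0.0661) and macrophages (-0.282) early, and brown fat (-0.672), interferon response (0.186), adipocytes (-0.0581), macrophages (0.0318) and fibroblasts (0.0327) between the windows. With the lymphocyte covariate lipolysis reversed late (0.0479) and between the windows (0.00833). Leaving out an array reversed lipolysis late (range -0.0596 to 0.0596) and heat shock proteins early (range -0.0555 to 0.0622). The main means were -3.25e-05 for lipolysis late, -0.0454 for lipolysis between the windows and 0.0034 for heat shock proteins early. In each of these camera gave the direction opposite to the mean, so only the sign of the mean reversed and not the direction of the test.

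Of single named genes called between the windows, 294 of the combinations of gene and alternative kept the call and 237 lost it at the same sign. Fos and Tfrc each lost it in 3 of 20 alternatives, the 2 covariates together, without 18 h and without 24 h. For called lists 39 combinations in the early window, 35 in the late window and 43 between the windows lost the call at the same sign. These counts include fry in place of camera, which asks another question.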

Other observations

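No test in this part was chosen after the result was seen. Lists of cell division and protein folding were not called in any window by camera. Mitosis genes averaged 0.06 above vehicle in the early window (adjusted p = 0.093) and -0.02 in the late window (adjusted p = 0.982), and DNA replication genes 0.02 and -0.01 (adjusted p = 0.605 and 0.965). Endoplasmic reticulum chaperones averaged 0.05 and -0.02 (adjusted p = 0.0935 and 0.766), and heat shock proteins 0.0034 and 0.00063 (adjusted p = 0.613 and 0.999). Between the windows the adjusted p was 0.171 for mitosis, 0.733 for DNA replication, 0.0872 for chaperones and 0.733 for heat shock proteins.

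Interferon response genes averaged 0.13 at 1 h, with 24 of 31 above both vehicle arrays, and -0.10 at 3 h, with 21 below both, and the list was not called in the early (mean -0.0061, adjusted p = 0.312) or late window (mean -0.06, adjusted p = 0.0837). Circadian clock genes averaged 0.02 and -0.03 (adjusted p = 0.542 and 0.602) in the early and late windows. A mean cannot show a change in a list whose members go both ways, and 10 of these genes were higher and 5 lower early. The test of fry for change in either direction gave the clock list adjusted p = 0.0388 early, 0.762 late and 0.00878 between the windows. A difference in clock genes is therefore not excluded. Lipolysis and fatty acid oxidation averaged 0.05 and -3.25e-05 in the early and late windows (camera adjusted p = 0.613 and 0.213), and growth factors and Wnt ligands 0.05 and -0.02 (adjusted p = 0.315 and 0.982). Solute and water transporters averaged 0.11 and 0.02 (adjusted p = 0.162 and 0.766), with the water channel gene Aqp5 at 1.18 ± 0.266 (SE) in the early window (adjusted p = 0.5). Neutrophil and mast cell markers averaged 0.08 and -0.06 (adjusted p = 0.548 and 0.213), endothelial markers 0.0028 and -0.03 (adjusted p = 0.613 and 0.462), and nerve and Schwann cell markers 0.06 and 0.05 (adjusted p = 0.455 and 0.398). The mean, the median and the test differed in sign for heat shock proteins in all 3 window comparisons, for DNA replication, cytokines, growth factors and lipolysis in the late window, for T lymphocyte, endothelial and nerve markers in the early window, and for lipolysis, myoepithelial and nerve markers between the windows, and for heat shock proteins, estrogen-responsive genes, circadian clock genes, neutrophil and mast cell markers and fibroblast markers with all E2 arrays, and none of these was called. Erythrocyte and skin and hair follicle markers had fewer than 5 tested genes and were not tested.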
